A study of Mus musculus with 4 samples.

How the data were processed

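Chromatin bound by INO80, the ATPase that gives its name to a nucleosome remodelling complex, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse spermatocytes of the first wave of meiosis. Per the labels, the mice were DBA/2J x C57BL/6J F1 animals. Fertilysin was given for 7 days from 2 dpp (days after birth), which holds germ cells at the spermatogonial stage, and retinoic acid at 9 dpp released them into meiosis together. Testis cells were collected 8 days after retinoic acid, at early zygotene, and spermatocytes were enriched on a 28% Percoll gradient. There were 2 INO80 libraries and 2 input libraries. The labels number the replicates but do not say how many animals each pool held, so the spread between replicates can be partly technical. Dates written in the deposited peak names differ between the INO80 replicates, and replicate and date cannot be separated. Library protocols in the labels describe an adaptase kit for the INO80 samples that the input samples do not list.

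The submitters' processing notes name fastp, BWA, Picard 2.21.2, SAMtools 1.11, MACS2 2.2.7.1 and deepTools 3.4.3 with the builds GRCm38 and mm10, without roles or settings. Read numbers were deposited per library in rounded form, per the file headers. Peaks of each INO80 replicate came from the authors as a separate broad peak list, with a deposited fold enrichment, a −log10 p and a −log10 q per peak. The deposited score column of those lists held 10 times the −log10 q, truncated. Which control entered the peak calling is not given in the sources used here. The deposited fold, score and −log10 values are the peak caller's own and were used to describe, rank or filter peaks. The authors also deposited 1 peak set made from both replicates and kept at an irreproducible discovery rate (IDR) below 0.05 according to its title. It is called the reproducible set here. For each of its peaks the authors gave the nearest gene, the distance from the peak centre to the transcription start site (TSS) and an annotation class, but no signal and no IDR value. The deposited enrichment over annotation and repeat classes gives overlaps in bp, the natural log of observed over expected bp, a signed log p score and a p-value, per the file headers. The deposited functional annotation table gives a fold enrichment with raw and adjusted p-values per term. A curated list of meiotic genes and a table of selected genes near peaks were deposited as symbols and positions.

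Gene positions came from the RefSeq gene table of GRCm38.p6, the build the submitters name, restricted to the 21887 protein-coding genes on chromosomes 1 to 19, X and Y. The table used here has no strand. For the deposited distances, all 1339 peaks within 1 kb that the authors placed in an intron, an exon or a 5' UTR had a positive distance, so positive was read as downstream. Coordinates are those of the authors' tables. No genome sequence was used here, so the planned tests of sequence composition and of CpG-matched backgrounds were not run. The planned IDR limit of 0.01 could not be set without IDR values, and a q of 0.001 or less in both replicates took its place.

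Replicate peaks were called shared at an overlap of at least 1 bp. The share was set against 1000 random placements of the other replicate's peaks between the first and last peak of each chromosome, with a one-sided permutation p. Spearman's rho and Pearson's r of the fold were computed across shared peaks, which are not independent replicates. A gene counted as occupied when a reproducible peak assigned to it lay within 1 kb of its TSS. Each of 24 gene lists, written before the data were examined, was tested against all other protein-coding genes with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment over the 24 lists. The lists held 660 symbols in total, of which 4 found no gene in the table. The same test was applied to the curated meiotic genes and to X-linked against autosomal genes. Intervals of shares are 95% Clopper-Pearson intervals and cover counting error only. Genes are the units of these tests, not replicates, and both replicates enter 1 peak set.

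The genes named were fixed by rule before the data were examined. Up to 4 occupied members of each list were taken by peak signal. Up to 2 unoccupied members in alphabetical order were added where fewer than 50% were occupied. Added to these were all INO80 complex members, the 10 strongest promoter peaks and the 10 strongest of the authors' selected genes. The 5 enriched and 5 depleted annotation classes with the smallest p and the 10 terms with the smallest adjusted p completed the rule. An item that the rule names is not reported here. As the reproducible set holds no signal, signal was the mean of the fold of the strongest overlapping peak in each replicate.

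The list test was tested on simulated occupancy of the 21887 genes and 24 lists. With an odds ratio of 4 planted in 4 lists in each of 50 simulations, the median estimate was 4.07, and 60% of planted and 0.222% of unplanted lists were called. Simulated genes were occupied independently at a common rate outside the planted lists. Differences between promoters, such as CpG content, were not simulated, so the 0.222% need not hold for the real lists. Depletion was not planted, so the power to call it was not measured. In simulated peak lists with 250 planted overlaps, 257 were found. Alternatives covered the overlap rule, stricter peak thresholds, a TSS window of 5 kb, assignment of every gene with either annotated end within 1 kb of a peak, another background, and each replicate's own peak list, with gene ends, in place of the reproducible set. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, with figures from matplotlib 3.10.9. The input libraries enter no comparison beyond their read numbers.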

Results

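INO80 occupancy was measured by ChIP-seq in synchronised mouse spermatocytes at early zygotene, the stage at which homologous chromosomes begin to pair and double-strand breaks (DSBs) are repaired by recombination. The data comprised 2 INO80 libraries and 2 input libraries. INO80 replicate 1 held 134500000 reads, of which 98100000 mapped uniquely. INO80 replicate 2 held 125200000 reads with 82600000 mapped uniquely. Input 1 and input 2 had 70400000 and 39600000 uniquely mapped reads, all rounded as deposited. Positions refer to GRCm38, and fold enrichments are the peak caller's own values as deposited by the authors.

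The first comparison asked how far the INO80 replicates located the same regions. INO80 lay at 5123 regions in replicate 1 and at 7836 in replicate 2. Of the replicate 1 regions, 4722 (92.2%, 95% interval 91.4 to 92.9) overlapped a replicate 2 region, against 0.754% for randomly placed regions. Of the replicate 2 regions, 4656 (59.4%, interval 58.3 to 60.5) overlapped a replicate 1 region, against 0.493% at random. Both one-sided permutation p were 0.000999, the smallest that 1000 placements can give. Placements were uniform, whereas 74.9% of replicate 1 and 69.9% of replicate 2 peaks lay within 1 kb of a gene end. Any 2 libraries enriched at gene ends would exceed such placements, so this p does not measure agreement specific to INO80. The 3180 replicate 2 regions without a partner were narrower and weaker within that list, with a median width of 718 bp and a median fold of 2.93. Those with a partner had medians of 1380 bp and 4.35. Across the 4722 shared replicate 1 regions, fold enrichment correlated between replicates with a Spearman's rho of 0.685 and a Pearson's r of 0.716 on the log2 scale. These are correlations across peaks, which are not independent replicates. Fold was higher in replicate 2 at 89.1% of the shared regions, with a median of 4.35 against 3.29 in replicate 1.

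**Figure D1:**
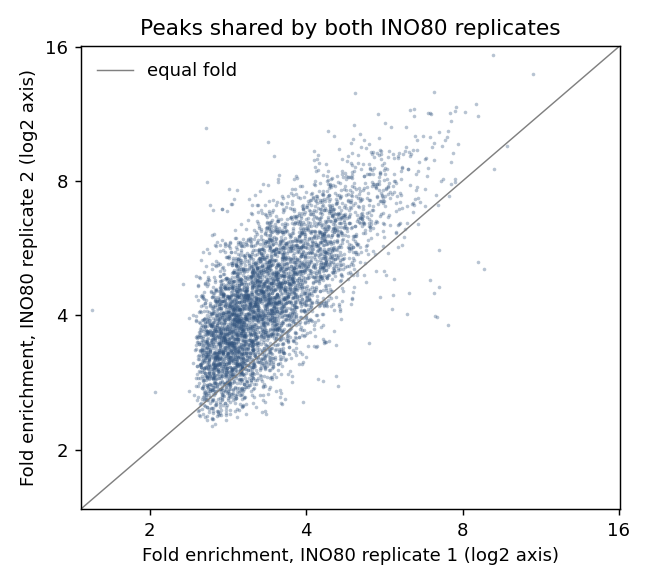
Fold enrichment of each shared INO80 peak in replicate 1 (horizontal, log2 axis) and replicate 2 (vertical, log2 axis), with 1 point per peak and a line of equal fold. The 4722 points rise together, with a Spearman's rho of 0.685, and 89.1% lie above the line, with a higher fold in replicate 2.

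The next comparison asked where in the genome reproducible INO80 binding lay. INO80 sat mostly at gene starts that carry CpG islands, the GC-rich stretches found at many promoters. Of 2847 reproducible peaks, 2297 (80.7%, 95% interval 79.2 to 82.1) had their centre within 1 kb of a TSS, and 292 (10.3%) lay farther than 5 kb away. Peak centres fell mostly inside the gene: 1772 of the 2297 (77.1%, interval 75.4 to 78.8) were downstream of the TSS, and the median offset was 238 bp. By annotation class, 877 peaks (30.8%) lay in promoters, 788 (27.7%) in introns, 587 (20.6%) in exons, 314 (11.03%) in 5' UTRs and 170 (5.97%) between genes. Non-coding transcripts held 53 peaks, transcription end sites 44 and 3' UTRs 14. Protein-coding gene ends within 1 kb of the peak were found for 79.9% of reproducible peaks, against 6.15% for random placements (one-sided permutation p = 0.000999, the smallest possible). The same share was 74.9% for all replicate 1 peaks and 69.9% for all replicate 2 peaks. Placements were again uniform, so the p for gene ends does not measure a preference specific to INO80.

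**Figure D2:**
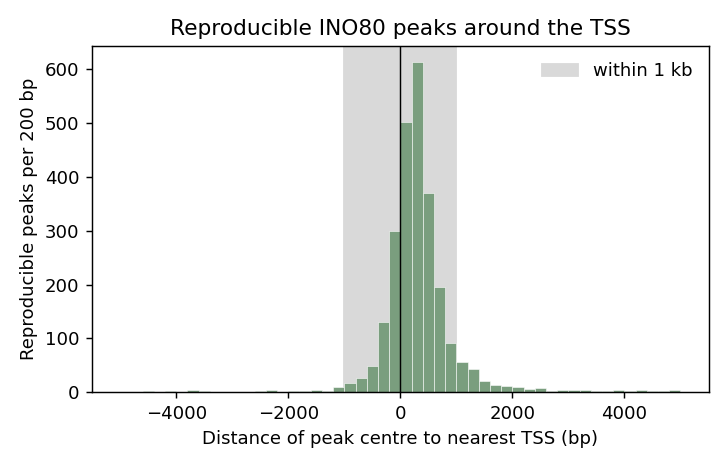
Number of reproducible INO80 peaks per 200 bp (vertical) by the distance of the peak centre to the nearest TSS in bp (horizontal, positive downstream), drawn to 5000 bp on either side. The grey band spans 1 kb around the TSS, which held 2297 of 2847 peaks, and the bulk lies just downstream of it.

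In the authors' deposited table of annotation classes, the 5 enriched classes with the smallest p were CpG islands, promoters, exons, protein-coding exons and 5' UTRs. CpG islands were overlapped by 2794 of the 2847 peaks, with 90.6 times the expected bp in the authors' deposited table. Peaks covered 27.0% of all CpG island bp, computed from the same deposited table. Observed over expected bp was 21.9 for promoters, 42.7 for 5' UTRs, 8.74 for protein-coding exons and 8.53 for all exons in the authors' deposited table. The 5 depleted classes with the smallest p there were intergenic sequence (0.125 of the expected bp) and the retroelement groups LINE (0.0149), its L1 family (0.00953), LTR (0.0301) and its ERVK family (0.0147). The expectation counts bp only, and 54.7% (input 1) to 72.9% (INO80 replicate 1) of reads mapped uniquely. Whether reads could be placed in these repeats was not examined, so the ratios do not show that INO80 avoids them. GC-rich low-complexity sequence was the repeat class with the smallest enrichment p, at 71.8 times the expected bp and with 1042 peaks in the authors' deposited table. Introns stood slightly below expectation (natural log ratio -0.11), a direction that depended on the genome size behind the expectation.

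Among the 10 strongest reproducible promoter peaks, Fgfr1, a fibroblast growth factor receptor, had the highest mean fold, with 10.9 in replicate 1 and 13.9 in replicate 2. That peak spanned chromosome 8, 25518104 to 25520238, centred 412 bp from the TSS in the 5' UTR. Sox18, a transcription factor of vascular development, had folds of 9.15 and 15.3 at chromosome 2, 181669929 to 181673319, in the promoter. Arhgap39 (folds 7.05 and 12.7, intron), Fam53a (8.56 and 11.2, intron), the purinergic receptor gene P2ry1 (8.08 and 11.4, exon) and the connexin gene Gja3 (7.78 and 11.7, promoter) followed. The other 4 were Aplp2 (9.74 and 9.59, intron), the proteasome subunit gene Psma7 (7.74 and 11.5, promoter), Xpc (7.61 and 10.9, promoter) and the transcription factor gene Cebpd (6.86 and 11.4, exon). Xpc encodes the damage sensor of global nucleotide excision repair, and its peak lay on chromosome 6, 91514498 to 91516241. Although classed as promoter, this peak was centred 519 bp downstream of the Xpc TSS, so class and distance need not refer to the same transcript. The same holds for the promoter peaks of Psma7 (215 bp) above and of Wt1 (777 bp), Sun2 (292 bp) and Rbbp4 (281 bp) below.

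The authors' table of selected genes near INO80 peaks asked which repair, chromatin and meiotic genes were bound, and named 81 genes, 42 under DNA repair, 30 under chromatin remodeling and 9 under meiosis I. By mean fold, Xpc led this table, ahead of Usp1, a deubiquitinase of the Fanconi pathway (folds 6.97 and 9.56, 5' UTR, chromosome 4, 98922205 to 98925854). Next were Tigar (6.10 and 8.42, intron), the cytosolic DNA sensor gene Cgas (4.95 and 8.42, non-coding transcript), Shisa2 (4.86 and 7.65, exon), Zbtb1 (5.76 and 6.65, promoter) and Hmga1 (4.64 and 7.36, promoter). Rbbp4, a histone chaperone shared by several chromatin complexes (5.63 and 6.19, promoter), Bach1 (6.00 and 5.68, intron) and Wrnip1 (4.19 and 7.40, exon) completed the 10. The table was selected by the authors from these peaks, so it is no independent evidence that such genes are preferred.

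Occupancy of gene groups was then compared with the genome. Reproducible INO80 peaks lay within 1 kb of the TSS of 2173 of 21887 protein-coding genes (9.93%). Spermatogonia markers, genes of the mitotic germ cells that precede meiosis, were the 1 list of 24 that passed the test. Of 27 members, 11 (40.7%, 95% interval 22.4 to 61.2) were occupied, an odds ratio of 6.26 (interval 2.62 to 14.4, Fisher's exact test, adjusted p = 0.000624). The strongest peaks were at Pou3f1 (folds 4.88 and 7.44, exon, chromosome 4, 124656527 to 124660210), the stem cell factor receptor gene Kit (4.81 and 7.22, intron, chromosome 5, 75574271 to 75577224), the GDNF receptor gene Ret (4.14 and 6.04, 5' UTR) and Foxo1 (3.67 and 6.19, exon). Bcl6b and Dnmt3a were members without a reproducible peak. The other 23 lists did not pass after adjustment, and promoter CpG content could not be matched because no genome sequence was used here.

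**Figure D3:**
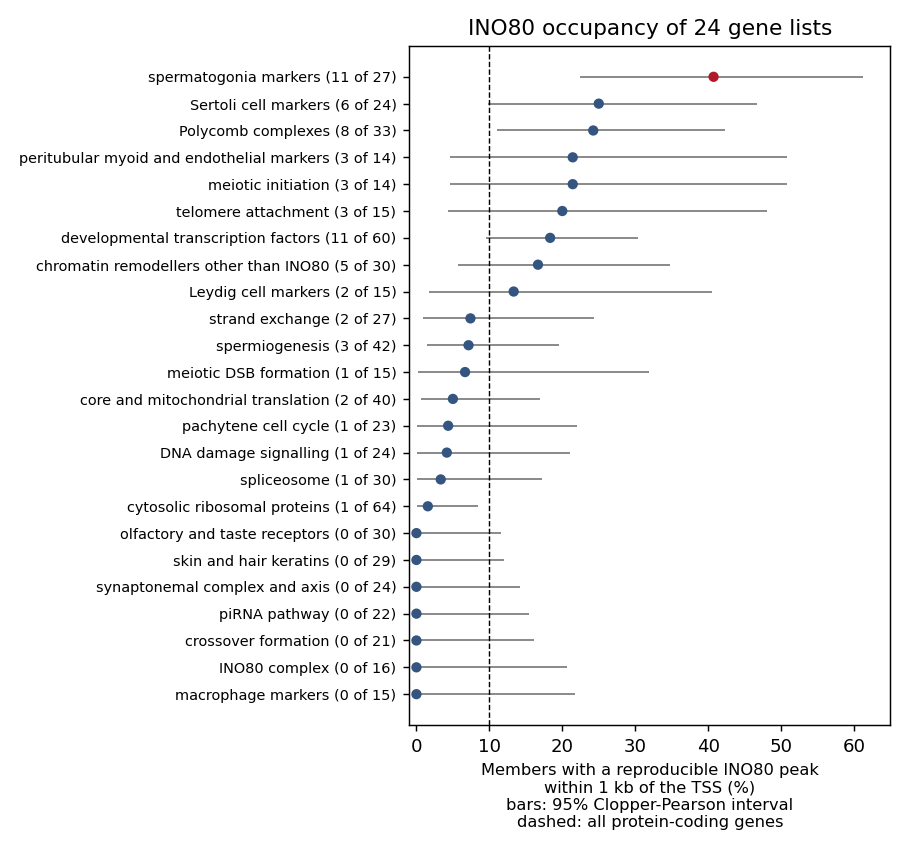
Percentage of members of each of 24 gene lists with a reproducible INO80 peak within 1 kb of the TSS (horizontal), with 95% Clopper-Pearson intervals as bars and the value for all protein-coding genes, 9.93%, as a dashed line. Spermatogonia markers, the red point at 40.7%, passed the adjusted test, and each other list is blue.

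Few reproducible peaks lay at genes of meiotic recombination and synapsis. Among 15 genes of meiotic DSB formation, Mei1 alone had a reproducible peak (folds 3.14 and 5.02, intron), and Ankrd31 and Cxxc1 had none. Among 27 genes of strand exchange, Xrcc3 (4.55 and 4.91, promoter) and Mnd1, a partner of the meiotic recombinase Dmc1 (3.49 and 4.41, intron), were occupied, and 4930432K21Rik and Brca1 were not. Of 24 DNA damage signalling genes, H2ax, the histone variant phosphorylated around breaks, was occupied (3.06 and 4.29, annotated by the authors as a transcription end site), whereas the kinase genes Atm and Atr were not. No peak lay at the 24 genes of the synaptonemal complex and axis, among them 4930447C04Rik and Fkbp6, which allows a share of up to 14.2%. None was assigned to the 21 genes of crossover formation, among them Brdt and Ccnb1ip1 (up to 16.1%), or to the 22 of the piRNA pathway, among them Asz1 and Btbd18 (up to 15.4%). By gene ends, 1 of the 21 crossover genes lay within 1 kb of a reproducible peak, and 4 lay near a peak in both replicates' own lists. Adjusted p values of these 6 lists in Fisher's exact test ran from 0.358 to 1, so none was distinguishable from the genome in the reproducible set at these list sizes. In each replicate's own list, 1 of the 24 synaptonemal complex and axis genes lay within 1 kb of a peak, which was below the genome in replicate 2 (odds ratio 0.113, 95% interval 0.00275 to 0.699, adjusted p = 0.0233) but not past the threshold in replicate 1 (odds ratio 0.178, adjusted p = 0.205) in Fisher's exact test. Direction turned in replicate 1 for DSB formation (5 of 15, odds ratio 2.05) and crossover formation (5 of 21, 1.28), neither past the threshold. In replicate 2 these were 4 of 15 (0.950) and 4 of 21 (0.614). Strand exchange, DNA damage signalling and piRNA genes stayed below an odds ratio of 1 in both, without passing.

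Telomere attachment genes included 3 occupied members of 15 (20.0%, Fisher's exact test, adjusted p = 0.362). They were Sun2 (folds 4.25 and 5.63, promoter), Syne2 (4.23 and 5.07, intron) and Sun1 (3.53 and 3.91, intron), all parts of the bridge between nuclear envelope and cytoskeleton, and Acd and Dynlt1b had no peak. Meiotic initiation genes had 3 of 14 occupied (21.4%, adjusted p = 0.358, Fisher's exact test), the retinoic acid receptor genes Rara (3.94 and 5.76, promoter) and Rarg (3.83 and 4.19, promoter) and Dmrt1 (3.83 and 5.54, intron), without Bhmg1 and Ccna1. The direction of that list depended on the assignment, with an odds ratio of 2.48 here, 0.593 (1 of 14) by gene ends, and 0.683 and 0.435 (2 of 14 each) over the lists of replicates 1 and 2. Of 23 pachytene cell cycle genes, Cpeb1 was occupied (3.90 and 4.11, intron), and Aurka and Aurkb were not (adjusted p = 0.826, Fisher's exact test). Spermiogenesis genes, used after meiosis, had 3 of 42 occupied (adjusted p = 0.868, Fisher's exact test), Odf2 (4.45 and 4.60), Spaca1 (3.53 and 3.63) and Catsper2 (3.10 and 3.87), without Acr and Acrv1.

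None of the 16 INO80 complex genes had a reproducible peak at its promoter (0%, up to 20.6%, Fisher's exact test, adjusted p = 0.558). These were Ino80, Ino80b, Ino80c, Ino80d, Ino80e, Actr5, Actr8, Ruvbl1, Ruvbl2, Actl6a, Actb, Nfrkb, Mcrs1, Tfpt, Yy1 and Uchl5. In the replicates' own lists, 4 of the 16 lay within 1 kb of a peak in replicate 1 (odds ratio 1.37) and 2 in replicate 2 (0.373), with Actr5 alone in both. Among 30 other chromatin remodellers 5 were occupied (16.7%, adjusted p = 0.397, Fisher's exact test), with the strongest peaks at Arid1b (3.35 and 5.86, exon), Chd2 (3.96 and 5.20), Chd7 (3.70 and 4.73, 5' UTR) and Chd6 (3.21 and 4.47, intron), and none at Arid1a or Arid2.

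Polycomb complexes, which silence developmental genes, had 8 of 33 members occupied (24.2%, odds ratio 2.91, 95% interval 1.13 to 6.67), with an unadjusted p of 0.0135 and an adjusted p of 0.153 in Fisher's exact test. The strongest were Rbbp4, Pcgf5 (4.75 and 7.08, intron), Pcgf2 (4.38 and 6.52, promoter) and Ring1 (4.68 and 5.70, promoter), and Aebp2 and Bmi1 had none. Within 1 kb of a peak in the replicates' own lists were 15 of the 33 in replicate 1 (odds ratio 3.42, adjusted p = 0.0054) and 20 in replicate 2 (4.03, adjusted p = 0.000812), both past Fisher's exact test. Developmental transcription factors had 11 of 60 occupied (18.3%, odds ratio 2.04, interval 0.956 to 3.99, adjusted p = 0.224, Fisher's exact test), with Neurog2 (4.69 and 4.62, exon), Hoxd13 (4.68 and 4.31, promoter), Tbx3 (4.15 and 4.77, promoter) and Irx3 (3.29 and 5.47, exon) strongest and Atoh1 without a peak. With a TSS window of 5 kb, 19 of the 60 were occupied and that list passed the test (odds ratio 3.78, adjusted p = 0.000318, Fisher's exact test). It also passed over the peaks of replicate 1 (25 of 60, odds ratio 2.94, adjusted p = 0.00127) and of replicate 2 (44 of 60, odds ratio 7.23, adjusted p = 6.12e-12) in Fisher's exact test.

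Markers of the somatic testis cells that a spermatocyte preparation can hold were compared in the same way. Sertoli cell markers had 6 of 24 occupied (25%, odds ratio 3.03, 95% interval 0.983 to 7.98, adjusted p = 0.160, Fisher's exact test), the strongest at Dmrt1, Kitl (3.95 and 4.88, promoter), Wt1 (3.54 and 4.16, promoter) and Sox9 (3.18 and 4.42, exon), with none at Amh or Amhr2. When every gene with an end within 1 kb of a peak counted, 9 of the 24 were occupied and the list passed (odds ratio 4.64, adjusted p = 0.0071, Fisher's exact test). Leydig cell markers had 2 of 15 occupied, Scarb1 (3.30 and 5.47) and Fdx1 (3.96 and 3.70), but not the steroidogenic genes Cyp11a1 and Cyp17a1. Peritubular myoid and endothelial markers had 3 of 14, the VEGF receptor genes Flt1 (4.75 and 6.36) and Kdr (3.27 and 4.55) and Egfl7 (2.98 and 4.12), but not Acta2 or Cdh5. None of 15 macrophage markers was occupied, Adgre1 and Aif1 included. Adjusted p of these last 3 lists lay between 0.358 and 0.787 in Fisher's exact test.

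Housekeeping and silent control lists had few reproducible peaks. Of 64 cytosolic ribosomal protein genes, Rpsa alone was occupied (3.38 and 3.59), against none at Rpl10 and Rpl10a, with an odds ratio of 0.144 (95% interval 0.00358 to 0.831), an unadjusted p of 0.0192 and an adjusted p of 0.153 in Fisher's exact test. In the replicates' own peak lists, 22 of the 64 lay within 1 kb of a peak in replicate 1 and 25 in replicate 2, and the direction turned, with odds ratios of 2.15 (adjusted p = 0.0311) and 1.68 (adjusted p = 0.149) in Fisher's exact test. Core and mitochondrial translation genes had 2 of 40, Eif4e (4.54 and 6.29) and Mrpl12 (3.61 and 3.88), without Eef2 and Eif2s1. Of 30 spliceosome genes, Sf3b1 was occupied (3.88 and 3.83), and Cdc5l and Ddx23 were not. No peak lay at 30 olfactory and taste receptors, Tas1r1 and Tas1r2 included, or at 29 skin and hair keratins, Krt1 and Krt10 included, which allows shares of up to 11.6% and 11.9%. Adjusted p ran from 0.273 to 0.571 for these 4 lists in Fisher's exact test. Translation genes had 10 of 40 near a peak in each replicate's own list (odds ratios 1.37 and 0.871 in replicates 1 and 2). Spliceosome genes had 7 and 9 of 30 (1.25 and 1.12), and neither list passed Fisher's exact test there. In the replicates' own lists, keratins again had 0 of 29 near a peak and stood below the genome in both (adjusted p = 0.0213 in replicate 1 and 0.000812 in replicate 2, Fisher's exact test). The receptors had 1 of 30 in each, below the genome in replicate 2 (adjusted p = 0.00735) but not past the threshold in replicate 1 (adjusted p = 0.0797) in Fisher's exact test.

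The authors' own curated list of meiotic genes was tested against the genome with the same rule. Of its 139 protein-coding genes, 7 (5.04%, 95% interval 2.05 to 10.1) were occupied, an odds ratio of 0.479 (interval 0.189 to 1.02, Fisher's exact test, p = 0.0624). The 7, named after their values were seen, were Antxr1, Ercc4, H2ax, Mnd1, Mxi1, Sun1 and Sun2, with mean folds from 3.67 at H2ax to 4.94 at Sun2. Mxi1 shares the alias Mad2 with another listed gene, Mad2l1, which was not occupied. In a test chosen after seeing the data, over all peaks of replicate 2, 25 of the 139 were within 1 kb of a peak and the odds ratio was 0.571 with a p of 0.00999, whereas over those of replicate 1 it was 0.687 with a p of 0.133 in Fisher's exact test.

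The X chromosome, present in 1 copy and largely unpaired in male meiosis, was nearly free of INO80 peaks. It carried 15 of the 2847 reproducible peaks, or 0.0879 per Mb, the lowest density among X and the 19 autosomes, whose lowest was 0.731 on chromosome 14 and median 1.14. Of 966 X-linked protein-coding genes, 12 (1.24%, 95% interval 0.643 to 2.16) were occupied, against 10.5% of autosomal genes. The odds ratio was 0.108 (interval 0.0554 to 0.189, Fisher's exact test, p = 5.41e-30). X ranked lowest in each replicate as well, with 36 peaks (0.211 per Mb) in replicate 1 and 119 (0.697 per Mb) in replicate 2, where autosomal medians were 2.12 and 3.17 per Mb. Over all peaks of replicate 2 the depletion of X-linked genes was less deep (odds ratio 0.237). Chromosome Y had no reproducible peak, none in replicate 1 and 5 in replicate 2.

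**Figure D4:**
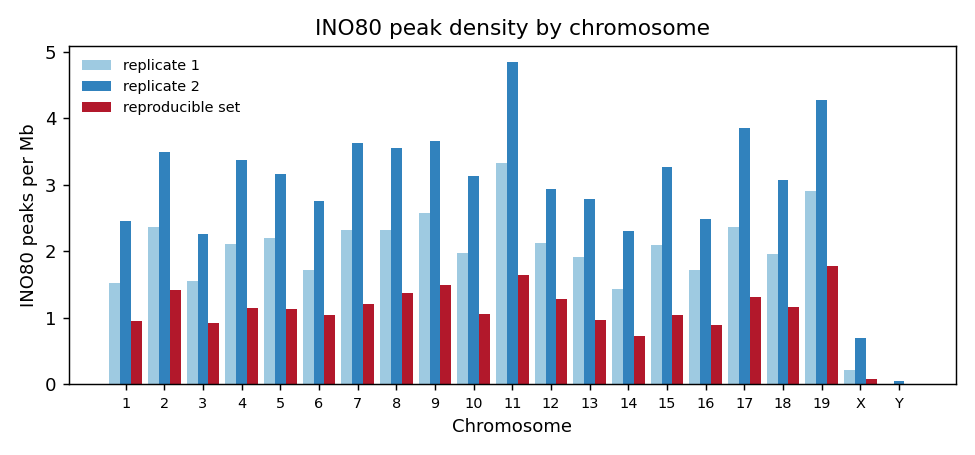
INO80 peaks per Mb (vertical) on each chromosome (horizontal) in replicate 1, replicate 2 and the reproducible set, over the span from the first to the last protein-coding gene. X lies below every autosome in all 3 sets, at 0.211, 0.697 and 0.0879 peaks per Mb.

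Functional terms of the peak genes were taken from the authors' deposited table. Developmental and transcriptional terms led it. Multicellular organism development held 273 genes at 2.25 times the background (adjusted p = 5.1e-37 in the authors' deposited table). It was followed there by negative regulation of transcription from RNA polymerase II promoter (210 genes, 2.44-fold), DNA-templated transcription (403 genes, 1.81-fold), positive regulation of transcription from RNA polymerase II promoter (254 genes, 2.16-fold) and regulation of DNA-templated transcription (444 genes, 1.65-fold). Axon guidance had the largest fold of the 10 leading terms in the authors' deposited table (69 genes, 3.93-fold, adjusted p = 3.68e-22). Positive regulation of DNA-templated transcription (157 genes, 2.31-fold), regulation of transcription from RNA polymerase II promoter (117 genes, 2.50-fold), the KEGG pathways in cancer (111 genes, 2.36-fold) and cell differentiation (173 genes, 1.88-fold) completed the 10 in the authors' deposited table. Chromatin remodeling held 17 genes at 1.82-fold with an adjusted p of 0.264 in the authors' deposited table. Of its 881 biological process and KEGG terms, 291 had an adjusted p below 0.05, and 0 named meiosis, recombination, the synaptonemal complex or DNA repair. Which terms were tested but left out is not given, so this does not show that such genes lack peaks. The authors' selected genes near peaks included 42 under DNA repair.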

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

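Choices made after seeing the data were the q limit of 0.001 in both replicates, assignment by gene ends for location, curated and X-linked genes, each replicate's own list for the curated genes, the pooled lists, the list without shared aliases, the X test without gene models and the larger genome size. No paired analysis was possible because the input libraries have no peak values to set against the INO80 libraries. The planned IDR limit of 0.01, the CpG-matched backgrounds and the sequence composition were not run. Of 206 alternative values, 137 kept direction and side of the threshold or stayed within their range, the cause of the others was not tested unless stated, and list values below are odds ratios. Fold correlation and X-linked depletion held under each alternative tried. Replicate overlap stayed above random placement in each, but its size moved with the lists compared. With top peaks of equal number in each list, 74.9% of replicate 1 and 74.7% of replicate 2 peaks overlapped. At a q of 0.001 or less in both lists the shares were 94.9% and 49.5%. Peaks within 1 kb of a TSS rose from 80.7% to 89.7% with a 5 kb window, which a wider window must do. Peaks within 1 kb of either gene end made up 79.9% of the reproducible set and 69.9% to 74.9% of each replicate's own list. The number of lists above the genome was 1, against 2 with a 5 kb window, 3 with assignment by gene ends and 4 over either replicate's list (spermatogonia, Polycomb, developmental factors and, by replicate, ribosomal or Sertoli). The number below was 0, against 1 and 3 over the lists of replicates 1 and 2 (keratins in both, and in replicate 2 also olfactory and taste receptors and the synaptonemal complex and axis). In the reproducible set even 0 of 30 receptors gave an unadjusted p of 0.0682 in Fisher's exact test. Lists of that size or smaller could therefore not be called below there. The higher genome shares of the replicates' lists allow such a call, so the 0 is no evidence against depletion. A background of genes named by any table, 2173 of them occupied by construction, put 0 lists above and 24 below. It turned spermatogonia markers to 0.329, Sertoli 0.159, Leydig 0.0736, myoid and endothelial 0.131, Polycomb 0.152, developmental factors 0.104, other remodellers 0.0947, telomere attachment 0.12 and meiotic initiation 0.131. That background was made of genes with peaks, the lists themselves and the authors' selected genes. Its direction was thus largely set in advance, and these turns are no evidence about the lists. With gene ends, meiotic initiation turned to 0.593 and spermiogenesis to 1.04. The replicates' own lists also use gene ends, so both choices change there, and direction turned in at least 1 for meiotic initiation (0.435 to 0.683), Leydig (0.63 to 0.653), myoid and endothelial (0.683 to 0.712), ribosomal (1.68 to 2.15), spliceosome (1.12 to 1.25), INO80 complex (0.373 to 1.37), DSB formation (0.95 to 2.05), crossover (0.614 to 1.28), pachytene cell cycle (0.725 to 1.14), translation (0.871 to 1.37) and pooled housekeeping lists (1.28 to 1.69, from 0.278). The pooled recombination and synapsis lists (0.341) ranged from 0.544 to 0.855, and the call was lost over replicate 1. The curated meiotic genes ranged from 0.571 to 0.687, past the threshold over replicate 2. The intron log ratio turned from -0.11 to 0.192 with a genome of 2697255124 bp in place of 2000000000. Peaks of replicate 2 lay near 27.7% of protein-coding genes and those of replicate 1 near 19.6%, so a gene without a reproducible peak is not shown to be unbound.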

Other observations

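Gene families by symbol root, a grouping chosen after seeing the data, were compared in reproducible INO80 occupancy, and most were not distinguishable from the genome. Of 274 families with at least 10 members, 8 stood above the genome and 2 below at an adjusted p under 0.05 in Fisher's exact test. Klf genes, zinc finger regulators of growth and differentiation, had 9 of 17 members occupied (52.9%, adjusted p = 0.000975, Fisher's exact test). The others above were Kcnk potassium channels (7 of 14), Dock exchange factors (6 of 11), Galnt glycosyltransferases (7 of 17), Chst sulfotransferases (6 of 14), Adamts proteases (7 of 19), Sox transcription factors (7 of 19) and Zbtb zinc finger genes (11 of 41). Their adjusted p ran from 0.0118 for Kcnk to 0.0468 for Chst, Adamts, Sox and Zbtb in Fisher's exact test, close to the threshold. By gene ends, occupied members were 4 in Dock, 6 in Kcnk, 6 in Adamts and 10 in Sox. The counts of Klf, Galnt, Chst and Zbtb did not change. The genome share by that rule was 11.5%, and these counts were not tested. Olfr olfactory receptors had 0 of 1110 members occupied and Vmn vomeronasal receptors 0 of 355.

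The 5 widest reproducible peaks were assigned to 9530036O11Rik (11343 bp), Irx5 (10471 bp), Lhx2 (10188 bp), Ebf3 (10147 bp) and Dmrta2 (10058 bp). The 21 reproducible peaks within 5 kb of the listed developmental transcription factors had a median width of 2456 bp, against 1782 bp for 2414 other peaks, and a median mean fold of 4.31 against 4.38. That comparison was prompted by the widest peaks, so it is given without a test. Ribosomal protein genes often lay near peaks that did not enter the reproducible set. Within 1 kb of a peak in both replicates' own lists were 17 of 64, and 2 of those 17 lay near a reproducible peak. For ribosomal, translation and spliceosome genes pooled it was 5 of 29, against 61.1% of the other genes near a peak in both lists, a comparison prompted by the ribosomal counts and given without a test. Their strongest peaks had a median fold of 3.15 in replicate 1 and 3.20 in replicate 2, against 3.32 and 4.29 over all 3895 genes near a peak in both.

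The authors' curated list of meiotic genes holds symbols that share an alias. Mxi1, a Max-interacting repressor, and Shisa2 both carry the RefSeq alias Mad2, also an alias of the spindle checkpoint gene Mad2l1 on the same list. Mxi1 was occupied and Mad2l1 was not. Without the symbols that share an alias, 6 of 121 genes were occupied and the odds ratio was 0.472 (Fisher's exact test, p = 0.0673), close to the 0.479 of the full list.

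In the 3 patterns weighed next, each test was chosen after the data had been seen. Those of replicate depth, input depth and CpG islands were chosen with their own values known, and for the others the bound was written before the value was computed. No biological explanation was tested, since the design holds 1 condition.

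The X chromosome had few INO80 peaks (odds ratio 0.108). Predicted gene models and multicopy families are argued against, since without them the odds ratio was 0.119 with an upper 95% limit of 0.263, whereas the single X of male cells may lower the evidence per peak. In replicate 2, 8.80% of X-linked genes lay near a peak, and the upper limit of 10.8% was below the 21.2% of autosomal genes near peaks with at least 2 times the lowest −log10 p, but not below the 10.6% at 4 times. Replicate 1 gave 2.59% (upper limit 3.80%), against 9.29% and 1.82%. How far 1 copy lowers the evidence is unknown, so copy number cannot be told apart from lower binding on X.

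Genes of recombination and synapsis, 5 lists pooled after seeing the data, had 4 of 110 members occupied (odds ratio 0.341, Fisher's exact test, p = 0.024). The assignment of 1 gene per peak could hide occupied genes, and with every gene end within 1 kb counted the odds ratio was still 0.444 (Fisher's exact test, p = 0.0498), with an upper 95% limit of 1.00 that leaves it only just open. A strict reproducibility threshold could also lower weakly bound groups. Near a peak in both replicates' own lists were 13 of the 110 (11.8%), against 17.8% of all protein-coding genes. Of those 13, 5 (38.5%) lay near a reproducible peak, against 60.8% over all genes near a peak in both, and these shares were not tested. Over all replicate 2 peaks the upper 95% limit of the odds ratio was 0.900, which met the bound written before it was computed. That limit rests on a list pooled after seeing the data and on 1 library. The replicate 1 list gave an odds ratio of 0.855, so the threshold stays open too. CpG islands remain a candidate explanation, since reproducible peaks covered 27.0% of island bp in the genome and the islands of single genes were not analysed here. Low occupancy in the reproducible set was not particular to recombination and synapsis genes. The pooled ribosomal, translation and spliceosome lists had 4 of 134 members occupied (odds ratio 0.278, Fisher's exact test, p = 0.0035). Over the replicates' own lists that pool had odds ratios of 1.69 in replicate 1 and 1.28 in replicate 2.

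Replicate 2 had 7836 peaks against 5123 in replicate 1. Depth of the INO80 libraries, counted as uniquely mapped reads, is argued against, since replicate 1 had 15500000 more. How many reads entered the peak calling is not given in the sources used here, so depth at that step stays open. Input depth could matter, as input 1 had 30800000 more uniquely mapped reads than input 2, but which input served which replicate is not given in the sources used here, and this cannot be told apart from a difference in immunoprecipitation.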
